A study of Mus musculus with 384 samples.

How the data were processed

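Single regulatory T (Treg) cells from mouse ear skin were profiled by plate-based RNA sequencing, with wells of 10 cells and wells without a cell as controls. The deposited values are counts of reads per gene and well, held in 1 matrix of 384 wells and 50556 gene symbols, of which 30597 had a count in any well. Per the labels' protocols, cells were sorted into lysis buffer, RNA was cleaned on beads, cDNA was primed with oligo dT, extended by template switching and amplified for 24 cycles, and tagmented libraries received another 12 cycles. Reads were processed with Trimmomatic 0.39, STAR 2.7.3a and SAMtools 1.12 against mm39, per the submitters' processing notes. The counting tool, its strand setting and the annotation were not given in the sources used here. Genes that overlap or share sequence with a copy, such as the haemoglobin and MHC class I genes, are therefore uncertain where counting split their reads. The labels' protocols mention no molecular identifiers, so PCR copies of 1 molecule count as several reads, and the intervals and limits given here cover counting error only. Constant T cell receptor genes appeared under the symbols Tcra and Tcrb.

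Wells were assigned to vehicle or imiquimod and to plates from the labels. The labels gave no treatment for wells with 10 cells or no cell, which entered no comparison between treatments. The design text names 2 mice per treatment without tying a plate to a mouse. The plate was therefore the replicate, with 2 plates per treatment, and p-values for single genes and for shares measure the spread between plates. The list tests with camera, described below, compare a list with the other genes. Their p-values also rest on the correlation assumed between genes. Plates are nested in treatments, so differences between whole plates cannot be told apart from treatment except by the spread between the 2 plates of a treatment.

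The tests, thresholds, gene lists, cell type markers and rule for named genes were fixed before the data were examined. Single-cell wells with at least 500 genes detected and at least 10000 counts were kept, which left 202 cells. No doublet caller was run, since wells were filled by sorting. Kept cells held between 47481 and 5946386 counts. Counts were summed over the kept cells of each plate, giving sums of 90448592 and 99396458 for vehicle and 67319087 and 99183184 for imiquimod. The sums were tested with edgeR's quasi-likelihood test after its default expression filter and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels of single genes are given in TMM-normalised CPM (counts scaled to the total of the sum), log2 fold changes are imiquimod over vehicle with the standard error (SE), and summed levels of lists are unscaled CPM.

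For the Penk class, cells at 10 CPM of Penk or more were set against cells with 0 Penk counts within each plate, with the plate as a block. Penk itself was left out of the count of calls. The interaction of this class with treatment was tested in the same sums. Shares per plate were compared by an exact two-sided permutation test, whose smallest possible p is 0.333 with 2 plates against 2. The 16 state lists and 14 cell type lists were fixed in advance. Lists with at least 3 genes tested entered camera with a preset correlation between genes of 0.01, and fry and camera with an estimated correlation were run beside it. Cells were clustered by the Leiden method at resolution 0.6 on 20 components and 15 neighbours of 2000 variable genes.

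Genes were named by rule. For treatment, the 12 genes per direction of largest fold change among those past the threshold were to be named. They also had to show no overlap between the plates of both treatments and detection in 25% of the kept cells of 1 treatment. Ribosomal, mitochondrial and uncharacterised genes and variable receptor segments were left out. Places left went to the genes of smallest p under the same conditions, which took all 24 places because no gene passed. For the Penk class, the same sign in every plate replaced the absence of overlap, and again no gene passed. Up to 4 genes per list, with those of highest level where none passed, and 16 genes of Treg and T cell biology were always named. Genes outside the rule are said to be chosen after their values were seen. The values of some genes that the rule names are not reported here.

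Alternatives comprised DESeq2 and its size factors, limma on the mean log2(CPM + 1) per cell, no expression filter, other filters on cells, thinning of each cell to 410000 counts and leaving out each plate in turn. Further alternatives were chosen after seeing the data. These were sums of the number of cells with a count, each gene without its highest cell per plate, plates without their 2 cells of most interferon genes, a filter on T cell receptor or CD3 counts, and removal of trends over gene span and expression level. Gene spans came from GENCODE M21 of GRCm38, an older assembly than mm39, and served as a property only; 12967 of 14462 tested genes (89.7%) matched by symbol. No coordinates are given, because the matrix holds symbols alone.

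The fits were tested on simulated counts with 200 changed genes. Simulated genes took their dispersion from the fit's trend over expression level, in a fit with a common dispersion of 2.71. At this spread edgeR recovered 0 of 100 genes changed 4-fold and 0 of 100 genes changed 16-fold among the 14462 genes of the treatment comparison. With a dispersion of 0.05 it recovered 97.0% and 100.0%. For the Penk class fit of 6716 genes, the simulation likewise recovered 0 of 100 and 0 of 100 at the trended dispersion of those sums (common dispersion 4.79). At 0.05 it recovered 97.0% and 100.0%. A log2 shift of 2 given to the simulated interferon list was recovered by camera in the treatment comparison at an adjusted p of 4.389e-05, with 0 other lists called. Simulated genes were drawn independently, whereas the estimated correlation within the real interferon list was 0.195. This recovery therefore says nothing about false calls from correlated genes. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9.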

Results

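Treg cells, the Foxp3-expressing CD4 T cells that restrain immune responses, were sorted from ear skin on day 3 of topical treatment with 5% imiquimod or vehicle. Imiquimod activates Toll-like receptors and gives a psoriasis-like skin inflammation in mice. The series title names enkephalins, the opioid peptides cut from the product of Penk, as the means by which a population of Treg cells acts on nociception. The wells lay on 4 plates, and each held 87 single cells, 4 wells of 10 cells and 5 wells without a cell. Vehicle and imiquimod had 2 plates each. Vehicle single-cell wells held 204466197 counts in all and those of imiquimod 202013154, wells of 10 cells held 68425970 and empty wells 3954843.

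Imiquimod cells yielded fewer detected genes per well than vehicle cells on both plates. The median was 780.0 and 860.0 genes on the vehicle plates and 381 and 501 on the imiquimod plates (820.0 ± 56.6 against 441 ± 84.9, SD, n = 2 plates each). The exact two-sided permutation p of 0.333 is the smallest that 2 plates against 2 allow. Median counts per well were 526780, 731288, 363915 and 1258812 in the same order. Thinned to 410000 counts, with 33, 21, 44 and 23 shallower wells left out, the medians were 866, 784, 494 and 428.5 genes. Kept were 62 and 58 vehicle cells and 38 and 44 imiquimod cells, or 69.0% ± 3.25 and 47.1% ± 4.88 of wells (exact p = 0.333, two-sided, n = 2 plates each). Kept cells had median gene numbers of 1040.0, 1503, 975 and 1093. All 16 wells of 10 cells passed the same filter, with a median of 6623.5 genes. Of the 20 empty wells 1 passed, 4 had no count, and the median of all 20 was 316 counts. Empty wells differed between plates, with at most 355 counts on vehicle plate 1. Their median was 144027 counts on vehicle plate 2, 2824 on imiquimod plate 1 and 169279 on imiquimod plate 2. The highest empty wells of these plates held 1527760, 305565 and 711071 counts in the same order.

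**Figure D1:**
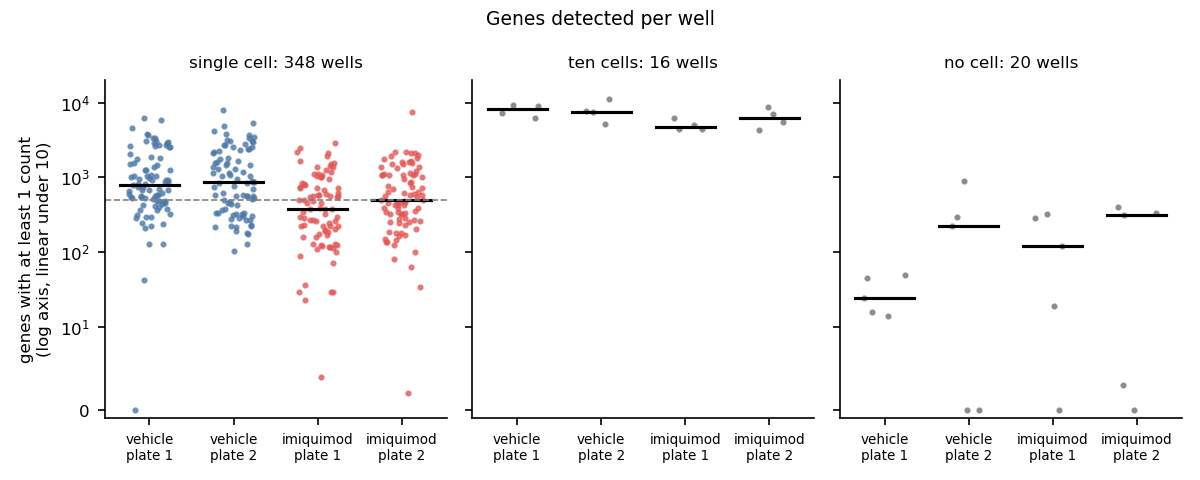
Genes with at least 1 count in each well (log axis, linear under 10) by plate, for 348 single-cell wells, 16 wells of 10 cells and 20 empty wells, with the median of each plate as a bar and the minimum of 500 genes as a dashed line. Single-cell medians lie at 780.0 and 860.0 on the vehicle plates and at 381 and 501 on the imiquimod plates.

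Transcripts of the Treg programme were frequent in the kept cells and mostly lacking from empty wells. Foxp3, the transcription factor that defines the lineage, had a count in 37.1% of the 202 kept cells (39.2% of vehicle and 34.1% of imiquimod cells). Ikzf2, which encodes Helios, was seen in 59.4%, Icos in 39.1% and Ctla4 in 28.7%. Gata3, a transcription factor of tissue Treg cells, was seen in 44.1%, and T cell receptor constant transcripts Tcra and Tcrb in 69.8% and 69.3%. Il2ra, the high-affinity receptor chain for interleukin-2, was seen in 59.2% of vehicle and 30.5% of imiquimod cells. Cd4 was detected in 30.0% and 14.6%, and Cd3e in 23.3% and 24.4%. Foxp3, Il2ra and Cd3e had no count in the 20 empty wells, which allows a share of up to 15.0%. Foxp3 and Il2ra were detected in all 16 wells of 10 cells and Cd3e in 15 of them. Detection depends on depth and on the gene yield that differed between plates, and these shares were not tested.

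The treatment comparison asked how the skin Treg transcriptome differed between imiquimod and vehicle. Immediate early genes, induced within minutes of a stimulus or of cell handling, were among the genes named as higher in imiquimod. Fos, a subunit of the transcription factor AP-1, reached 4055 and 2854 CPM on the imiquimod plates against 696 and 298 CPM on the vehicle plates (log2 fold change 2.80 ± 0.59, SE). Dusp1, a phosphatase that shuts off MAP kinases, reached 5343 and 3563 against 1140.4 and 695 CPM (2.28 ± 0.48). Ier2 stood at 1416 and 536 against 199 and 166.7 CPM (2.41 ± 0.95). Srgn, the core protein of secretory granule proteoglycan, stood at 4936 and 2427 against 862 and 428 CPM (2.51 ± 0.58). None of these passed edgeR's test over all genes, where each had an adjusted p of 0.42.

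Among the remaining genes named as higher, H2-T23 and H2-K1 belong to the fixed MHC class I presentation list and Ccr7 to the naive and recirculation list. H2-T23, which encodes the non-classical MHC class I molecule Qa-1, had a log2 fold change of 3.06 ± 0.98, and the classical H2-K1 had 0.97 ± 0.36. The splicing factor Srsf2 had 2.77 ± 0.91 and Dgat1, which makes triglycerides, 1.70 ± 0.61. Cep85, Dazap2 and the syndecan Sdc4 had 1.94 ± 0.69, 2.50 ± 0.90 and 2.47 ± 0.95. Ccr7, the chemokine receptor for lymph node entry, stood at 418 and 117.1 CPM on the imiquimod plates against 2.85 and 7.22 CPM, although fewer imiquimod cells had a count of it (11.0% against 28.3%). A single cell carried 87.2% of its counts on imiquimod plate 1, and a single cell nearly all of those on plate 2. Each of these genes had an edgeR adjusted p of 0.42.

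Among the genes named as lower in imiquimod, Il2ra stood at 657 and 978 CPM against 2621 and 1887 CPM on the vehicle plates (log2 fold change -1.46 ± 0.58). Traf1, an adaptor of tumour necrosis factor receptors, stood at 701 and 484 against 1865 and 1479 CPM (-1.50 ± 0.66) and was detected in 22.0% of imiquimod and 63.3% of vehicle cells. Ccdc88c, an inhibitor of Wnt signalling, stood at 14.1 and 226 against 1042 and 805 CPM (-2.94 ± 1.24). The other 9 fell near 0 on the imiquimod plates, so their levels are given and not their folds. Sdk1 and Gse1 stood at 182 and 83.7 CPM on vehicle plate 1, 159.7 and 259 CPM on vehicle plate 2, and at most 0.471 CPM on the imiquimod plates. Rnf216, Hs6st3, Sorcs3, Adgrv1 and Eprs lay between 55.4 and 195 CPM on the vehicle plates and at or under 0.342 CPM on the imiquimod plates. Tenm3 stood at 181 and 219.6 against 0.706 and 3.56 CPM and Pcdh9 at 2.68 and 167.1 against 0.15 and 0.118 CPM. Single cells carried much of some vehicle levels, with 99.2% of the Sorcs3 counts on vehicle plate 1 and 82.5% of the Rnf216 counts on vehicle plate 2 in 1 cell. The 9 genes still had counts in 3.66% (Eprs) to 34.1% (Tenm3) of imiquimod cells. These 12 lower genes had a median span of 445.5 kb, the 12 higher genes 7.68 kb and all tested genes 28.0 kb. Over all tested genes the median log2 fold change ran from 0.95 in the shortest 20% of genes to -1.60 in the longest 20%. The edgeR adjusted p was 0.42 or 0.43 for all 12, so none passed.

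Treg identity genes did not pass the test over all genes, although the plates of both treatments did not overlap for Foxp3, Gata3, Tnfrsf4, Ikzf2, Cd4 and Cd3e, as 33.3% of genes do by chance. Foxp3 stood at 1636 and 1224 CPM in imiquimod and 992 and 387 CPM in vehicle (log2 fold change 1.05 ± 0.72, edgeR adjusted p = 0.61). Gata3 had 1.87 ± 0.75 and Tnfrsf4, the costimulatory receptor OX40, 1.66 ± 0.69. Icos had 0.83 ± 0.65, Ikzf2 -0.65 ± 0.43 and Ctla4 -0.10 ± 0.87. Cd4 had -1.80 ± 1.27 and Cd3e 1.02 ± 1.16. The tissue repair factor Areg had 0.86 ± 1.17, Il1rl1, the receptor for interleukin-33, 0.35 ± 0.91, and the cytokine Il10 0.43 ± 1.00. Klrg1, Ccr8, Nr4a1 and Mki67 had 2.10 ± 1.24, -0.33 ± 1.38, 0.38 ± 0.62 and -1.89 ± 2.96. Isg15, an interferon-induced ubiquitin-like protein, stood at 1.41 and 0 CPM in vehicle and 0 and 39.4 CPM in imiquimod, and Penk at 0.547 and 1.39 against 4.60 and 0.0107 CPM. None of these genes passed edgeR's test.

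Over all 14462 genes tested, edgeR called 0 genes at an adjusted p under 0.05, and its smallest adjusted p was 0.42. At an unadjusted p under 0.05 it had 1669 genes, 249 higher and 1420 lower in imiquimod. The plates of both treatments did not overlap in 6473 genes (44.8%), against 33.3% by chance. DESeq2 called 3740 genes (968 higher, 2772 lower) and limma 0, with 2496 at an unadjusted p under 0.05. Without imiquimod plate 1, edgeR called 215 genes, and without imiquimod plate 2 it called 794, with 48 genes in both; each fit leaves 1 imiquimod plate, assumed to vary like the vehicle plates. Without vehicle plate 1 or 2 it called 0 and 0, with 98 genes at an unadjusted p under 0.05 in the former (75 higher, 23 lower) and a smallest adjusted p of 0.175 in the latter. The balance of higher and lower genes at an unadjusted p under 0.05 thus depended on the plates, and without an expression filter it was 416 higher and 467 lower. The common dispersion was 2.71, and the simulation at the fit's trend of dispersion recovered 0 of 100 genes changed 16-fold. A lack of calls therefore does not show a lack of change. The median log2 fold change of all tested genes was -0.26 under TMM and 0.11 under DESeq2's size factors, a shift of 0.37.

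**Figure D2:**
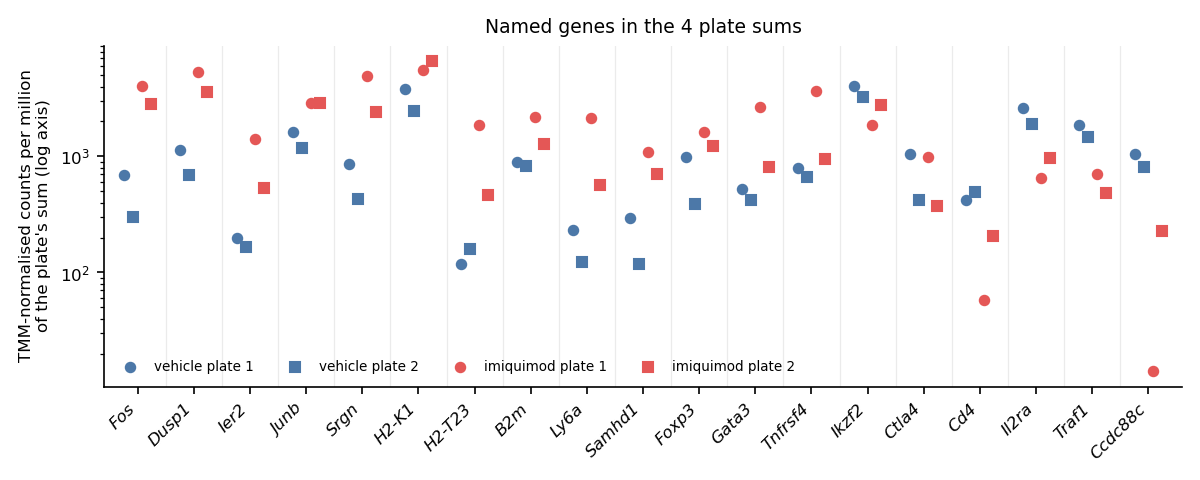
TMM-normalised CPM (log axis) of named genes in the sums of the 4 plates, circles for plate 1 and squares for plate 2 of each treatment. For Fos the imiquimod plates lie at 4055 and 2854 CPM and the vehicle plates at 696 and 298 CPM, while for Il2ra the imiquimod plates lie at 657 and 978 CPM and the vehicle plates at 2621 and 1887 CPM.

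Of 24 lists tested with camera, 3 rose in imiquimod, those of immediate early and stress genes, interferon response and MHC class I presentation. Of 28 immediate early and stress genes, 24 had a positive log2 fold change, with a median of 1.37 (camera adjusted p = 0.000155, and adjusted p = 0.717 with an estimated correlation). Fos and Dusp1 passed edgeR's test adjusted over the list alone (both 0.0063), Junb had a log2 fold change of 1.05 ± 0.48 and the chaperone Hspa8 0.80 ± 0.56. Of 55 interferon response genes, 40 were positive, with a median of 2.18 (camera adjusted p = 0.000726, and adjusted p = 0.717 with an estimated correlation). Ly6a had 2.93 ± 0.93, Samhd1, which degrades nucleotides against viruses, 2.12 ± 0.96 and Gbp4 -1.51 ± 1.52. Ifit3, chosen after its values were seen, was the 1 member past edgeR's test adjusted over the list alone (0.0466), at 0 and 0.423 unscaled CPM in vehicle and 162.1 and 751 CPM in imiquimod. Of 17 MHC class I genes, 14 were positive, with a median of 1.02 (camera adjusted p = 0.00735, and adjusted p = 0.717 with an estimated correlation), and 0 passed adjusted over the list alone. B2m, the light chain of MHC class I, had 1.02 ± 0.62 and H2-D1 0.40 ± 0.43. No member of any list passed over all genes in edgeR.

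The immediate early list was called with any plate left out, while the other calls depended on plates. With each gene's highest cell per plate left out, all 3 lists were still called (camera adjusted p = 0.00368 for interferon, 3.953e-05 for immediate early and 0.0016 for MHC class I), as they were in thinned cells and in cells of at least 1000 genes. The highest-cell setting added erythroid markers upward and the 1000-gene setting the tissue and effector Treg list upward. The interferon list's was 0.238 without imiquimod plate 2, where its median log2 fold change was -3.69 and that of all genes -6.56. It was 0.083 (median 1.29) without the 2 cells of most interferon genes on each plate, which were picked by the signal itself. The MHC class I list's was 0.0712 without vehicle plate 2 and 0.0853 without those interferon cells. With the trends over gene span and expression level removed, the immediate early list's was 0.555 and the MHC class I list's 0.774, with the latter pointing down, and counted by cells with a count the 3 were 0.26, 0.26 and 0.186. Removal of both trends also called Treg core (0.0497), T cell receptor and NF-kB activation (0.0209), homing and adhesion and cytokine receptors (0.031 each) downward and keratinocyte markers (0.0304) upward in camera. The rotation test fry, which asks whether a list's genes move one way on balance, called 0 lists. Camera called 11 lists without vehicle plate 1, 3 without vehicle plate 2, 4 without imiquimod plate 1 and 6 without imiquimod plate 2. None of the 3 medians changed sign under DESeq2's size factors.

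**Figure D3:**
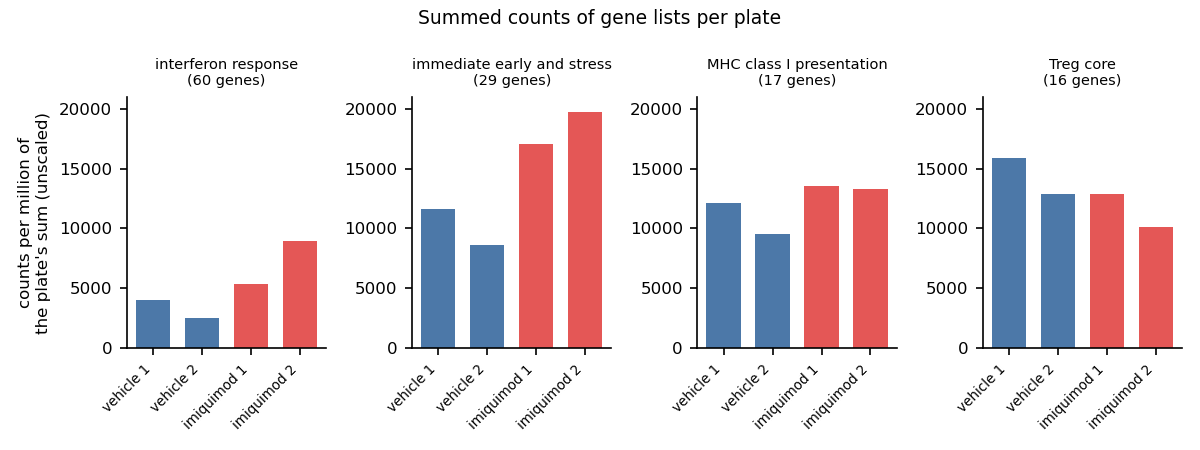
Summed counts of 4 gene lists in unscaled CPM of each plate's sum, 1 bar per plate without error bars. The immediate early and stress list lies at 11636 and 8619 CPM on the vehicle plates and 17049 and 19751 CPM on the imiquimod plates, and the Treg core list at 15887 and 12880.2 against 12920.3 and 10112 CPM.

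The other T cell lists did not pass camera with all plates and kept cells. Treg core, tissue and effector Treg and type 1 lists passed upward without vehicle plate 1 and without imiquimod plate 2. The T cell receptor and NF-kB activation list and the T cell markers passed upward without vehicle plate 1. Each of these fits leaves 1 plate in a treatment. The Treg core list had 10 of 15 members positive and a median log2 fold change of 0.84 (adjusted p = 0.286), while its unscaled sums ran the other way. Tissue and effector Treg genes, among them Tnfrsf9, Tnfrsf1b and Rora (0.88 ± 0.68, 0.64 ± 0.66 and -0.32 ± 0.56), were positive in 18 of 25 (median 0.55, camera adjusted p = 0.0781). The type 17 list had 3 of 12 positive (median -1.16, 0.392), with Ccr6 at -1.83 ± 1.66. The type 1 list had 6 of 9 positive (0.58, 0.286), with the protease Gzmb at 0.58 ± 0.70. T cell receptor and NF-kB activation had 20 of 31 positive (0.58, 0.286), with Nfkbia at 0.69 ± 0.55. The T cell markers had 5 of 9 positive (1.01, 0.286), with Cd2 at 1.73 ± 0.76 and Lck at 1.01 ± 0.78. The naive and recirculation list had 4 of 13 positive (-0.59, 0.986), with Il7r at -0.13 ± 1.07 and Satb1 at -0.73 ± 1.01. Adjusted over the list alone, 0 members of these lists passed edgeR's test.

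In the remaining state lists, medians, means and tests often differed in sign. Proliferation had 19 of 32 positive (median 0.61, mean -0.89, test up, camera adjusted p = 0.536), with the replication helicase subunits Mcm7 and Mcm3 at 3.38 ± 1.22 and 1.81 ± 2.20, of which 1 cell held 99.1% and 84.8% of the counts on imiquimod plate 1. Homing and adhesion had 11 of 23 (median -0.00, mean -0.75, test up, 0.536), with Vim at -0.00 ± 0.45. Cytokine receptors and signalling had 17 of 33 (median 0.25, mean -0.48, test up, 0.536), with Il2rg at 0.48 ± 0.64. Glycolysis had 10 of 20 (median -0.00, mean -1.15, test up, 0.536), with Ldha at 1.21 ± 0.62 and Pkm at 0.28 ± 0.56. Under DESeq2's size factors the homing and glycolysis medians were 0.64 and 0.41. Lipid and cholesterol synthesis had 9 of 20 (median -0.60, mean -0.15, test up, 0.444). The opioid peptide list had 3 of 6 positive (-0.60, 0.536), and Cpe, which trims peptide precursors, stood at 67.9 and 29.4 CPM in vehicle and 0 and 0 CPM in imiquimod, with 72.6% of its counts on vehicle plate 1 and all of those on plate 2 in 1 cell. The sex-linked list had 2 of 4 positive (-1.03, camera adjusted p = 0.66). Members past edgeR's test adjusted over the list alone numbered 0 in each.

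Markers of other skin cells were mostly low in level but not all rare. Adgre1, which encodes the macrophage marker F4/80, was detected in 32.5% of vehicle and 25.6% of imiquimod cells at 17.5 CPM or less, and Kit in 25.8% and 4.88%. Keratinocyte markers had 5 of 6 positive (median 2.83, camera adjusted p = 0.0781). They passed upward without vehicle plate 1, vehicle plate 2 or imiquimod plate 1, in fits that leave 1 plate in a treatment. Without imiquimod plate 2 their median was -9.77, where that of all genes was -6.56. Krt14, a keratin of basal keratinocytes, stood at 0 and 0 CPM in vehicle and 2.01 and 331 CPM in imiquimod, passed adjusted over the list alone (0.0225), and 98.9% of its counts on imiquimod plate 1 and all of those on plate 2 came from 1 cell. Neutrophil markers had 2 of 4 positive (median 0.13, mean -2.38, test up, 0.566), and Mmp9 was lower adjusted over the list alone (0.008), at 110.3 and 299 CPM in vehicle and 0.0214 and 0 CPM in imiquimod, with 48.0% and 80.9% of its vehicle counts in 1 cell per plate. Adjusted over the list alone, 0 members of the following lists passed edgeR's test. Macrophage or monocyte markers had 1 of 6 positive (-4.00, 0.344), and Lyz2 was detected in 4.46% of kept cells, fewer than Adgre1. Antigen-presenting cell markers had 2 of 5 (-0.53, and 0.01 under DESeq2's size factors; 0.98), with Cd74 detected in 42.5% of vehicle and 22.0% of imiquimod cells. Counted by cells with a count, this was the only list called, downward (camera adjusted p = 0.0429). Fibroblast markers had 2 of 6 (-1.36, 0.344), endothelial markers 0 of 3 (-3.42, 0.806) and erythroid markers 4 of 5 (0.36, 0.286). CD8 T cell, gamma-delta T cell, NK cell, B or plasma cell, mast cell and melanocyte or Schwann cell lists had fewer than 3 genes tested. Their sums were at most 1.53, 56.8, 11.7, 26.5, 273 and 149.2 unscaled CPM on any plate, and Cd8a was detected in 1.49% of kept cells. The B or plasma cell sum leaves out the immunoglobulin symbols Igh and Igk, which that list does not hold. Igh was detected in 67.6% and Igk in 77.5% of cells of the first cluster described below, and in 76.0% and 87.0% of the other cells.

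Penk transcripts, which encode the enkephalin precursor, were rare. At least 1 count was found in 11 of 202 kept cells, and 6 of these reached 10 CPM. These 6 were 1 of 62 and 1 of 58 vehicle cells and 4 of 38 and 0 of 44 imiquimod cells, where 0 of 44 allows a share of up to 6.82%. The mean share was 1.67% ± 0.0787 in vehicle and 5.26% ± 7.44 in imiquimod (SD, n = 2 plates each, difference 3.59 percentage points, exact two-sided permutation p = 1.0). From 1 count on, with 6 vehicle and 5 imiquimod cells, the share was 5.12% ± 4.96 and 6.40% ± 5.84 (difference 1.28, exact two-sided permutation p = 0.667). Without imiquimod plate 1 the difference in the Penk-detected share was -1.67, and without imiquimod plate 2 it was 8.86. The 11 cells held 446 Penk counts, and the highest cell had 52.7 CPM. No Penk count occurred in the 20 empty wells, and 2 of the 16 wells of 10 cells held 9 Penk counts in all.

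**Figure D4:**
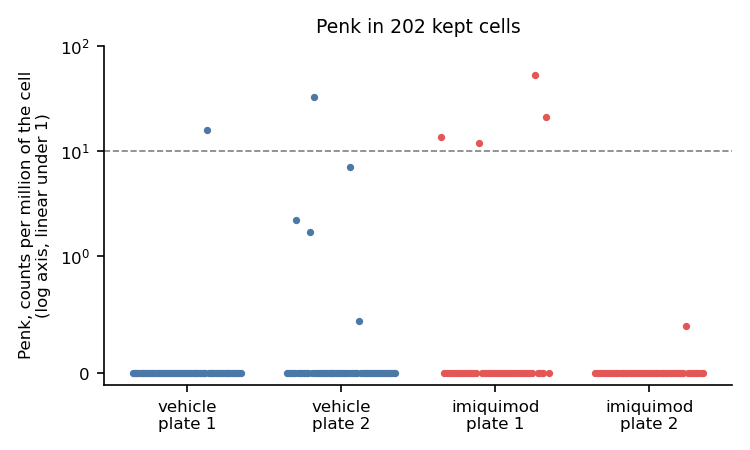
Penk in each of the 202 kept cells in CPM of the cell (log axis, linear under 1) by plate, with the class limit of 10 CPM as a dashed line. Of the 6 cells at or above the limit, 4 lie on imiquimod plate 1 and none on imiquimod plate 2.

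Cells with Penk counts also carried some Treg transcripts. Foxp3 had a count in all 6 cells at 10 CPM or more and in 10 of the 11 cells with any Penk count, against 65 of the 191 cells without (34.0%). In the 6 cells, Ctla4, Icos, Gata3 and Cd3e were each seen in 4, against 27.2%, 37.7%, 42.9% and 22.5% of the cells without Penk. Ikzf2 and Tnfrsf18 were each seen in 3, Il2ra in 2 and Tnfrsf4 in 1, against 58.6%, 29.3%, 47.6% and 28.3%. Areg, Il1rl1 and Mki67 were seen in 0. In the 11 cells Il1rl1 was seen in 3 (27.3%) and Areg in 2 (18.2%), against 27.2% and 20.4% of the cells without Penk. Of the 6 cells, 1 reached the limit with 1 Penk read among 47481 counts, and Foxp3 rested on 1 read in that cell and on 2 reads in another. The 11 cells had a median of 2433 genes and the other 191 a median of 1087, so depth differed between them. The class is a range and not a cell type, and 5 of the 11 cells lay under its limit.

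Penk-detected and Penk-undetected cells were compared within plates, on the question of which genes accompany enkephalin expression. Imiquimod plate 2 had no Penk-detected cell, so the 6 detected cells were set against the cells without a Penk count on the other 3 plates. Il1rl1 stood at 0 CPM in the detected cells of all 3 plates against 935, 1174 and 799.8 CPM in the undetected cells (imiquimod 1, vehicle 1, vehicle 2). Areg likewise stood at 0 against 1056, 427 and 624 CPM. Ikzf2 stood at 380, 703 and 1149 against 2400, 7735 and 6565 CPM (log2 fold change -2.88 ± 1.26). Il2ra stood at 54.0, 1879 and 0 against 876, 4899 and 4204 CPM. Tgfbr2, a receptor subunit for transforming growth factor beta, stood at 530.4, 446 and 1200.4 against 0.816, 216 and 97.1 CPM (4.10 ± 4.59). Foxp3 stood at 841, 1489 and 1277 against 1946, 1785 and 596 CPM (-0.13 ± 2.02), and H2-D1 at 4768, 7834 and 5655 against 5580.1, 6416 and 4802 CPM (0.10 ± 0.80).

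None of these genes passed edgeR's test. The other genes of smallest p with the same sign on every plate were Apbb1ip, Atp6v1f, Glmp, Polr2m, Prpf6, Rmnd5a, Smad2, Smim4, Trim30a, Trnau1ap and Ube2j1, higher in detected cells, with log2 fold changes from 2.51 to 5.90. The lower ones, apart from Il1rl1, were Ago2, Bcl2l1, Bhlhe40, Camk2b, Dennd4a, Fam110a, Kdm2b, Nav2, Rnf157, Sntb1 and Tnfrsf4. Kdm2b, a histone demethylase, stood at 0 CPM in the detected cells of all 3 plates against 567, 3209 and 2418 CPM and had the smallest edgeR adjusted p of the fit (0.142). Bcl2l1, which encodes the survival protein Bcl-xL, stood at 0, 0 and 0.145 against 1082, 2537 and 2001 CPM. Over 6716 genes edgeR called 0, with 1001 at an unadjusted p under 0.05, all lower in detected cells; DESeq2 called 4128 and limma 1349. Sums of 1 cell detect few genes, and the median log2 fold change was -8.84. Without imiquimod plate 1 edgeR called Camk2b alone, without vehicle plate 1 Tnfrsf4 alone, and without vehicle plate 2 no gene, with 17, 39 and 55 genes at an unadjusted p under 0.05. The interaction of class and treatment gave 0 genes in edgeR, 21 at an unadjusted p under 0.05, and 1251 in DESeq2. It compared 1 imiquimod plate with vehicle plates of 1 detected cell each.

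Of 17 lists tested between the Penk classes, 0 passed camera. MHC class I presentation came nearest (median -1.05, above the median of all genes, camera adjusted p = 0.0633), followed by proliferation (-12.85, 0.0793), T cell markers (-1.88, 0.0804) and homing and adhesion (-2.90, 0.168). Lipid synthesis, cytokine receptors and interferon response had camera adjusted p of 0.362, 0.434 and 0.477. The Treg core, tissue and effector Treg, type 1 and immediate early lists had 0.629. The type 17, T cell receptor and NF-kB, naive and glycolysis lists had 0.802, and antigen-presenting and erythroid markers 0.916. Medians and means of all 17 lists were negative, while 10 pointed up in camera, which compares a list with the other genes. With an estimated correlation 0 lists passed, and fry called MHC class I presentation alone, downward (adjusted p = 0.0423). Without imiquimod plate 1 camera called 4 lists, and without vehicle plate 1 or 2 it called 0 and 0. Adjusted over the list alone, edgeR called Capg, Tnfrsf18 and Tnfrsf4 of the Treg core list, Rora of the type 17 list and Gzmb of the type 1 list, all with negative fitted folds, and 0 members of the other 14 lists. Tnfrsf4 and Gzmb had detected sums without a count, and Gzmb stood at 2184 CPM in the detected cell of vehicle plate 1 against 1759 CPM in the undetected cells. Tnfrsf18 had counts in 3 of the 6 detected cells, all on imiquimod plate 1. They held 12495, 17365 and 4835 reads, each a level above the 1424 unscaled CPM of that plate's kept cells. In lists too small for camera, with fewer than 3 genes tested, Sfn (keratinocyte, 0.0366), Lyz2 and Tyrobp (macrophage or monocyte, 0.0464 and 0.0381) were also under 0.05 adjusted over the list alone. Their folds were negative. The adjustment did little there, since edgeR's unadjusted p was 0.0366, 0.0464 and 0.019. Over all 6716 genes, 1001 had an unadjusted p under 0.05, all lower in detected cells.

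Clustering divided the kept cells into 3 groups, with median gene numbers of 932, 985.5 and 2143 and with 30 cells in the second and 70 in the last. The first was led by Ctnna3, Cpa6 and Igh, the second by Dlgap1, Sgcz and Lingo2, and the last by Gapdh, Gm46174 and B4galnt2. None of the 10 leading genes of a cluster was in the fixed marker lists, which hold neither Igh and Igk, among the leaders of the first cluster, nor Tcrb, among those of the second. Igh was detected in 67.6% of cells of the first cluster and 76.0% of the other cells, and the clusters stayed unnamed. The first held 59.7% and 53.4% of vehicle and 36.8% and 45.5% of imiquimod cells, the second 12.9% and 10.3% against 21.1% and 18.2%, and the last 27.4% and 36.2% against 42.1% and 36.4%. The exact 95% binomial intervals for the first cluster were 46.5 to 71.9%, 39.9 to 66.7%, 21.8 to 54.0% and 30.4 to 61.2%, and no test was made.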

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

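All tests of causes in this part were chosen after the results were seen. Of the wells without a cell, 1 on vehicle plate 2 held 1527760 counts, the next highest there holding 428587, and it was past Dixon's test for a single extreme value. Of the wells of 10 cells on the same plate, 1 held 6182812 counts, with 4366035 in the next, and it was likewise past Dixon's test. Chance alone puts about 1 in 20 groups past this limit, both ends together, and the cause of either value was not tested. Neither well entered a comparison. Penk had 9 counts in all in the wells of 10 cells, from 2 of the 16 wells, and 0 in wells without a cell.

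Interferon response genes such as Ifit3, Ly6a and Samhd1, immediate early genes such as Fos and Dusp1 and MHC class I genes such as H2-T23 were called higher in imiquimod as lists, which Toll-like receptor activation could bring about, but with an estimated correlation the adjusted p was 0.717 for each. For the interferon list the camera adjusted p was 0.000751 with the trend over gene span removed. It was 0.0209 with the trends over span and expression level removed and 0.00368 with each gene's highest cell per plate left out. At the preset correlation, the list's call thus did not rest on these properties or on 1 cell per gene and plate alone. These p-values cannot argue against those causes, because with an estimated correlation the list was not called. With span alone removed the immediate early list was at 0.000693 and the MHC class I list at 0.0305, so their calls at the preset correlation did not rest on span alone. With both trends removed they were at 0.555 and 0.774. Expression level, alone or with span, is thus a candidate explanation for both, whose medians of 1.37 and 1.02 lay within those of random lists matched for both (0.82 to 2.28 and 0.71 to 2.49). Whether the interferon list rests on 1 plate or a few cells stayed open. Without imiquimod plate 2 the list's median was -3.69, although 2.87 above that of all genes. Cells of imiquimod plate 1 held a mean of 3.1 interferon genes, against 4.3 and 4.5 on the vehicle plates. The summed level of that plate was higher, at 5345 against 3998 and 2522 unscaled CPM. Without the 2 cells of most interferon genes per plate, picked by the signal itself, the list's median was 1.29 in place of 2.18 (camera adjusted p = 0.083).

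Foxp3 counts in 10 of the 11 cells with a Penk count were set against chance among cells of like gene numbers. In 10000 draws of cells from the same plates with similar gene numbers (median 2473 against 2433 genes), the mean was 5.81 Foxp3-positive cells. Only 0.31% of draws held 10 or more, a share not adjusted for the choice of Foxp3 after its counts in these cells were seen. It therefore gives no verdict on the number of genes as a cause, and Foxp3 rested on 1 or 2 reads in 2 of the cells. Total counts were not matched, with a median of 2696755 in the 11 cells and 1367921 in the other 191. The draws therefore cannot set read depth aside. Cells are not replicates, and no biological explanation was tested.

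For the Penk class comparison itself, the 6 sums allow 10 splits, too few for a share under 5%. The real split gave 0 genes in edgeR, as did the others that part every plate, and the highest other split, which does not, gave 19.

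Muc2, Krt19, Epcam and other gut epithelial genes made up 11.1% of all counts in the wells without a cell, which no comparison used, against 0.167% in single-cell and 0.0443% in 10-cell wells. The signal was also in compared cells, where 83 of 202 kept cells had over 3 counts, at most 8.56% of a cell's counts, and the list took 0.0209% of counts of kept cells on vehicle plate 1 and 0.436% on imiquimod plate 1. The list of 36 genes was drawn up after 9 of them had been seen in empty wells. Counts of the other 27 members had been looked at too, so they are no independent check. These 27 took 1.75% of counts in empty wells, 0.0806% in single-cell wells and 0.0259% in 10-cell wells. The share in single-cell wells was 0.046 of that in empty wells, and the share in empty wells was 21.8 times the larger of the other shares. Because the list was drawn up from genes seen in empty wells, these ratios cannot decide whether RNA of the sorted skin cells was the source. RNA from outside the sort, such as a gut sample handled with the same reagents or sequenced beside these plates, is a candidate explanation, with no biological one tested.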

How the results depend on the processing

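The number of cells with a count, the sums without the interferon cells or without each gene's highest cell, the filter on T cell receptor or CD3 counts, the removal of trends and, for lists, all filters on cells and thinning were chosen after the results were seen. For treatment, edgeR's 0 genes became 3740 with DESeq2, 9 without an expression filter and 17 with the number of cells with a count, and ran from 0 to 794 with 1 plate left out. For the Penk class, 0 genes became 4128 with DESeq2, 1349 with limma and 1 in thinned cells, and ran from 0 to 1 with 1 plate left out. The interaction's 0 genes became 1251 with DESeq2. The number of treatment lists called by camera was 3, and 0 with an estimated correlation, 0 with fry, 1 without the interferon cells (immediate early), 1 with the number of cells (antigen-presenting cell, down) and 6 with trends over span and level removed (4 of them down, and interferon the only one of the 3), and ran from 3 to 11 with 1 plate left out. The 0 Penk class lists became 1 with fry and ran from 0 to 4. For the interferon response list, the adjusted p was 0.717 with an estimated correlation, 0.799 with fry, 0.083 without the interferon cells and 0.26 with the number of cells, and ran from 1.464e-09 to 0.238 with 1 plate left out. For the immediate early and stress list it was 0.717, 0.389 with fry, 0.26 with the number of cells and 0.555 with both trends removed, and ran from 1.776e-05 to 0.00204. For the MHC class I presentation list it was 0.717, 0.616 with fry, 0.0853 without the interferon cells, 0.186 with the number of cells and 0.774, with the sign turned, with both trends removed, and ran from 0.000522 to 0.0712. The difference in the Penk-detected share ran from -1.67 to 8.86 with 1 plate left out and from 0.98 (thinned, from 1 count) to 11.25 (cells with Foxp3 and CD3 counts) with all plates, where the exact permutation p was 0.667 or 1.0. Clusters numbered 2 at resolution 0.3 and 7 at 1.0. Among named genes, Mcm3 ran from -13.52 to 2.90 in the treatment comparison, and the lower value passed in edgeR without imiquimod plate 1. In the Penk class comparison limma turned B2m (5.65), Foxp3 (6.56), H2-K1 (5.28), Junb (3.27), Klf6 (5.74), Lck (6.48) and Pkm (5.05) to higher in detected cells. Of 2044 values of treatment genes under other settings, 1750 kept direction and call, and of 1560 of the Penk class 1351 did. Not run were the Penk class from 50 CPM, which held 1 cell, and the interaction without 1 plate, which left no residual degrees of freedom. The causes of these shifts were not tested. Depth limited which genes a cell could show, and thinning to 410000 counts kept 182 of 202 cells. No paired analysis was possible because nothing ties a vehicle plate to an imiquimod plate and replicate numbers are only names.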

Other observations

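The count of cells per gene and the genes in this part were chosen after the results were seen. When each kept cell counted once per gene, 17 of 1988 genes differed between treatments in edgeR, 11 detected in more and 6 in fewer imiquimod cells. Hba-a1 and Hba-a2, the alpha chains of haemoglobin and markers of red blood cells, were among the 11. Hba-a1 was detected in 47.4% and 40.9% of imiquimod cells and in 1.61% and 17.2% of vehicle cells (log2 fold change 2.71 ± 0.47, edgeR adjusted p = 0.0055), and Hba-a2 in 26.3% and 22.7% against 1.61% and 8.62% (adjusted p = 0.0187). Hba-a1 was also found in 3 of the 20 wells without a cell. Dct, a pigment enzyme of melanocytes, was detected in 18.4% and 20.5% against 3.23% and 3.45% (edgeR adjusted p = 0.0119). Jaml, an adhesion molecule of leukocytes, was detected in 28.9% and 29.5% against 14.5% and 5.17% (0.0364), and Elapor1 in 36.8% and 52.3% against 6.45% and 24.1% (0.0107). The source of these transcripts was not tested.

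Prdm12, a transcription factor of nociceptive neurons, was detected in 48.4% and 34.5% of vehicle cells and in 7.89% and 0% of imiquimod cells (edgeR adjusted p = 0.0195). Zswim6 was detected in 40.3% and 53.4% against 7.89% and 11.4% (0.0345). Afm, a vitamin E carrier made in liver, was detected in 62.9% and 44.8% against 0% and 2.27% (0.00026). Afm had a count in all 5 empty wells of vehicle plate 1 as well.

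Kit, the mast cell receptor for stem cell factor, stood at 248 and 90.4 CPM on the vehicle plates and 6.48 and 6.83 CPM on the imiquimod plates. Hdc, which makes histamine in mast cells, went the other way in detection (15.8% of vehicle and 32.9% of imiquimod cells). Neither passed edgeR's test. Plate sums correlated with each other at 0.348 to 0.459 over genes, and wells of 10 cells yielded a mean of 7937 and 7827 genes on the vehicle plates and 4973.75 and 6391.75 on the imiquimod plates. Thinned to 410000 counts, the means of wells of 10 cells were 5849, 6026, 3553 and 5181 genes in the same order.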
